A study of Mus musculus with 6 samples.

How the data were processed

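Total RNA of submandibular glands, one of the major salivary glands, was measured in 6 female NOD mice aged 10 weeks, 3 with wild-type Myd88 (Myd88+/+) and 3 homozygous for the targeted allele (Myd88−/−). NOD mice develop autoimmune infiltrates of the salivary glands and the pancreas, and Myd88 is the adaptor through which most Toll-like receptors and the receptors of the interleukin-1 family signal. Each mouse gave 1 Clariom S array, a short-oligonucleotide array whose probe sets summarise whole transcripts, and the design text says that no technical replicates were run. RNA was isolated with a column kit and copied into labelled single-stranded cDNA, per the labels' protocols. The strain labels name a NOD.B6 background, so a segment around the targeted gene may come from another strain than the rest of the genome.

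The deposited values are log2 expression values from the robust multi-array average (RMA), computed by the authors in the Transcriptome Analysis Console, per the labels and the submitters' processing notes. The version of that software, the variant of RMA and the genome build of the array's annotation are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a set, so small differences between groups are shrunk near background and cannot be read at the top of the scale. The log2 scale was read from the values, which ran from 2.26 to a ceiling of 19.93. A probe set on that ceiling on every array is called saturated, no fold is given for it, and it counts as neither higher nor lower in a list. Scanner files were not used here.

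The table held 28846 probe sets, of which 6640 were control probe sets and were left out of the tests. Of the 22206 tested probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2634 were unnamed here. The Entrez identifiers of 19572 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, through which 0 symbols had to be updated, and which was used only for names and for which genes neighbour each other. For the 19505 named genes 1 probe set stood for the gene, the one with the highest mean over the 6 arrays, which left out 67 further probe sets.

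Groups were taken from the sample titles and strain labels. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, no covariates), as Myd88−/− minus Myd88+/+, with Benjamini-Hochberg adjustment over all tested probe sets and a call at an adjusted p under 0.05. A descriptive count took probe sets at least 2-fold apart at an unadjusted p under 0.05. All values are means with the standard deviation (SD) over the mice of a group. Single measures of the arrays were compared with a two-sided exact permutation test, which cannot give a p under 0.1 for 3 mice against 3. The number of arrays limits the precision of every value.

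Gene lists were tested with limma's camera, which compares a list with all other genes, with its preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 32 lists. Beside it stand camera with an estimated correlation, limma's fry, which tests a list without reference to other genes, and the number of members that pass limma's test adjusted over the list alone. The 32 lists held 722 distinct gene names, which matched 639 distinct genes with a probe set, some genes standing in several lists. They cover the Toll-like receptor pathway, its inflammatory targets, interferon responses, antigen presentation, leukocyte types, the cell types of the gland, tissues that lie next to it, RNA handling and the neighbours of Myd88. A list score of a mouse is the mean over members of the log2 value minus that member's mean over the 6 arrays. Genes within 10 Mb of Myd88 on chromosome 9 were compared with genes elsewhere by a two-sided Fisher's exact test.

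The genes named in the results follow a rule. It takes Myd88, then the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, or, where too few pass, those with the smallest unadjusted p in that direction, and then up to 4 members of each list with the smallest unadjusted p, up to 2 for lists of other cell types and of RNA quality. Predicted genes, clone names, olfactory and vomeronasal receptors, small RNAs and variable segments of antigen receptors were counted and not named. As no probe set passed, every gene named here did not pass limma's test over all probe sets. Groups, tests, lists, the naming rule and the alternatives were fixed before the data were examined, except where another choice is said to have been made later.

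The alternatives were quantile normalization, median centring and cyclic loess on top of the deposited values, leaving out the dimmest 30% or 50% of probe sets, an intensity trend with robust variances, array weights, no moderation of variances, the replicate number as a block and leaving out each mouse in turn. For the lists they were also an estimated correlation, fry, members of 1 list alone and the mean of a gene's probe sets. Leaving saturated probe sets out of the lists, and counting probe sets at an unadjusted p under 0.05 under each setting, were added after seeing the data.

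The procedure was tested on simulated data made for Myd88−/− against Myd88+/+ over 22206 probe sets, 200 of which were changed. It recovered 80% of the changes of log2 size 1 and 100% of those of log2 size 2, with 15 false calls among 195, and it called 4 of 4 lists shifted by 0.7 on the log2 scale and 0 of 27 unshifted lists. All 200 changes were placed in probe sets brighter than the median, with normal noise drawn from limma's moderated variances. The rates therefore say nothing about dim probe sets, or about genes that vary more between mice than those variances allow. The simulated probe sets vary independently of each other, so the result on lists says nothing about lists whose members vary together from mouse to mouse.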

Results

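Gene expression was measured in the submandibular glands of 6 female NOD mice aged 10 weeks, 3 Myd88+/+ and 3 Myd88−/−, with 1 array per mouse. The comparison asked which transcripts of the gland differ with Myd88 in a strain that develops autoimmune inflammation of the salivary glands. The median log2 value of an array lay between 6.0 and 6.1, and the 15 pairs of arrays correlated at r = 0.982 to 0.991 across probe sets, which are not independent replicates. No pair held identical values (0 of 15). The first principal component, with 33.4% of the variance, placed the Myd88+/+ glands between −32.45 and −10.11 and the Myd88−/− glands between 0.28 and 39.84. The span from the 10th to the 90th percentile of an array was 7.20 ± 0.10 log2 units (SD, n = 3) in Myd88+/+ and 6.97 ± 0.15 (SD, n = 3) in Myd88−/− glands (two-sided exact permutation p = 0.2). Myd88−/− replicates 1 and 3, at 25.74 and 39.84 on the component, had the narrowest spans, 6.95 and 6.83. They also ranked positive above negative control probe sets least often, in a share of 0.785 and 0.780 of pairs. Myd88−/− replicate 2, at 0.28, had a span of 7.13 and a share of 0.805. The component therefore does not part genotype from signal range or array quality.

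The targeted gene was examined first. The single Myd88 probe set read 7.81, 7.86 and 7.53 in Myd88+/+ replicates 1, 2 and 3 and 7.33, 6.80 and 7.47 in Myd88−/− replicates 1, 2 and 3. All 3 Myd88−/− values lay below the lowest Myd88+/+ value, by a mean log2 difference of −0.53, a 1.44-fold lower level. Without Myd88−/− replicate 2 the difference was −0.33, and leaving out each other mouse gave −0.67 to −0.47. The two-sided exact permutation p was 0.1, the smallest that 3 mice against 3 allow, and limma's adjusted p was 0.46, so the difference did not pass. The median of the background control probe sets was 5.55, below each of these 6 values. Whether this probe set lies in the deleted part of the gene is not given in the sources used here, and a probe set outside it checks nothing about the labels.

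Transcripts of macrophages, antigen presentation and the response to interferon-gamma were lower in Myd88−/− glands, as groups, than in Myd88+/+ glands. Macrophage and monocyte markers fell by 0.91 on the log2 scale on average, genes of MHC class I presentation fell by 0.89 and genes induced by interferon-gamma fell by 1.19. Among single genes, Pigr, the receptor that carries IgA across secretory epithelium, read 15.54 ± 0.58 (SD, n = 3) in Myd88+/+ and 11.89 ± 1.39 (SD, n = 3) in Myd88−/− glands, a 12.5-fold lower level. Cxcl9, a chemokine induced by interferon-gamma that attracts T cells, read 10.38 ± 2.32 and 6.30 ± 0.48 (SD, n = 3 each), and Cxcl13, which attracts B cells, read 10.46 ± 1.74 and 7.62 ± 0.22 (SD, n = 3 each), a difference of −2.84 (−3.58 to −1.88 without 1 mouse). Genes of fibroblasts and extracellular matrix, of myoepithelial and basal cells and of the ducts were also called lower, by −0.55, −0.34 and −0.19 on average. All of these calls came from camera with its preset correlation, and with an estimated correlation 0 lists were called, at a smallest adjusted p of 0.427. The duct call was also lost without Myd88+/+ replicate 1 (mean −0.12), without Myd88−/− replicate 1 (mean −0.12), after quantile normalization and after cyclic loess. In the myoepithelial and duct lists the scores of single mice overlapped between the groups. The secretory genes that mark the acini and the granular ducts were not called as groups.

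No single gene passed limma's test after adjustment. Of 22206 probe sets, 0 were higher and 0 lower at an adjusted p under 0.05, the smallest adjusted p being 0.128. At an unadjusted p under 0.05, limma counted 999 higher and 1233 lower probe sets, against 1110 in all that chance would give. Without variance moderation these counts were 904 and 845. With an intensity trend and robust variances it called 4 lower, Emp3, Rnase1, Ly6c1 and Tmem176a, each at an adjusted p of 0.0305, and with median centring 2 lower, Emp3 and Rnase1, at 0.0457. It called 5 lower without Myd88+/+ replicate 1, 1 without Myd88+/+ replicate 3 and 1 without Myd88−/− replicate 2. The adjusted p of Emp3 and of Rnase1 ran from 0.0305 to 0.603 over all settings tried, that of Ly6c1 to 0.631 and that of Tmem176a to 0.676. At least 2-fold apart at an unadjusted p under 0.05 were 16 higher and 161 lower probe sets, 177 in all, a count that reached 282 without Myd88+/+ replicate 1 and 318 without Myd88−/− replicate 2. The 2 groups did not overlap in 3351 probe sets (15.1%), where chance gives 10% on average for 3 against 3. How far that share moves between splits of the arrays was not tested.

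The 12 genes with the smallest p on the lower side did not pass limma's adjusted test. Of 123 genes named by rule, 43 had a group mean under the background control median of 5.55, which leaves the size of their differences uncertain, among them Rnase1, Clnk and Itgam here. In 25 of the 123 both group means lay under that median. Emp3, an epithelial membrane protein, had a log2 difference of −1.70 with a standard error (SE) of 0.20, from 9.14 ± 0.32 to 7.44 ± 0.11 (SD, n = 3 each, limma adjusted p = 0.128). Rnase1, a secreted ribonuclease, had −1.68 with an SE of 0.20, from 6.26 ± 0.29 to 4.59 ± 0.16 (SD, n = 3 each, limma adjusted p = 0.128). Ly6c1, a surface protein of monocytes and endothelium, had −1.26, and its neighbour in the gene family, Ly6c2, had −1.07. Such paralogs can share probes, so their separate values are uncertain. The adaptor genes Dok2 and Clnk, both of blood cells, had −1.27 and −0.89, and Itgam, an integrin of myeloid cells, had −1.36. Trp63, the transcription factor of basal epithelial cells, had −1.18, from 10.56 ± 0.09 to 9.38 ± 0.20 (SD, n = 3 each). Tmem176a had −1.10, Tmsb10, an actin-binding peptide, −1.18 and Islr, a gene of stromal cells, −1.51. With Pigr at −3.65, limma's adjusted p of these 12 genes lay between 0.128 and 0.321.

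On the higher side, most of the 12 genes with the smallest p were dim. Over all tested probe sets, the dimmer 50% had a median log2 difference of 0.09 and the brighter 50% of −0.07, so small differences follow signal level. The exceptions were Wfdc12 and Spata1. Wfdc12, a secreted protease inhibitor, read 15.79 ± 0.19 in Myd88+/+ and 17.06 ± 0.61 in Myd88−/− glands (SD, n = 3 each), a log2 difference of 1.27. Spata1, a gene of sperm development, read 7.15 ± 0.14 and 8.25 ± 0.10 (SD, n = 3 each), a difference of 1.10. The other 10 had Myd88+/+ means of at most 6.01, near the background control median of 5.55. They were Trp73, a relative of Trp63, with 0.91, the neuropeptide gene Vip with 0.93, Mtrf1 with 0.91, Tcerg1l with 0.81, Wee2 with 0.91, Ccdc51 with 0.91, Spink5 with 0.72, Mroh2b with 0.91, and the family members Btbd35f22 and Btbd35f21 with 1.23 and 1.09. Limma's adjusted p of these 12 genes lay between 0.309 and 0.339.

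**Figure D1:**
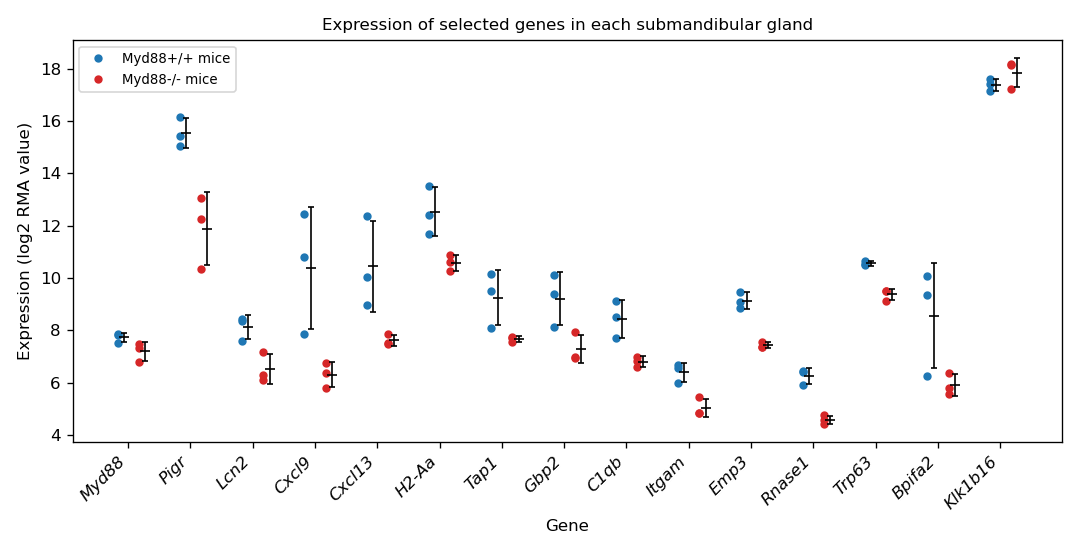
Log2 RMA values of 15 genes (x axis) in each submandibular gland (y axis, log2 scale), blue dots for the 3 Myd88+/+ mice and red dots for the 3 Myd88−/− mice, with black marks for the group mean and bars of 1 SD. Pigr, Cxcl9 and Cxcl13 lie lower in all 3 Myd88−/− mice, Cxcl9 spreads from 7.87 to 12.46 among the Myd88+/+ mice, and no gene passed limma's adjusted test.

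Of the 32 gene lists, 12 were called lower and 0 higher by camera with its preset correlation. With an estimated correlation 0 of 32 were called, the smallest adjusted p being 0.427, and fry called 0. Among the 12, scores of the groups overlapped for the type I interferon, B cell, NK, duct and myoepithelial lists. Their two-sided exact permutation p was 0.4, 0.3, 0.3, 0.3 and 0.2. In the other called lists the scores did not overlap, at 0.1, the smallest that 3 mice against 3 allow. In the macrophage, complement, MHC class I, MHC class II and interferon-gamma lists, Myd88+/+ replicate 3 had the highest score and Myd88+/+ replicate 1 the lowest of its group. The pooled score of their 80 genes was −0.12, 0.39 and 1.08 in Myd88+/+ replicates 1, 2 and 3 and −0.38, −0.46 and −0.51 in Myd88−/− replicates 1, 2 and 3. The spread between wild-type glands was therefore wider than that between Myd88−/− glands, and the plot of list scores shows it list by list.

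**Figure D2:**
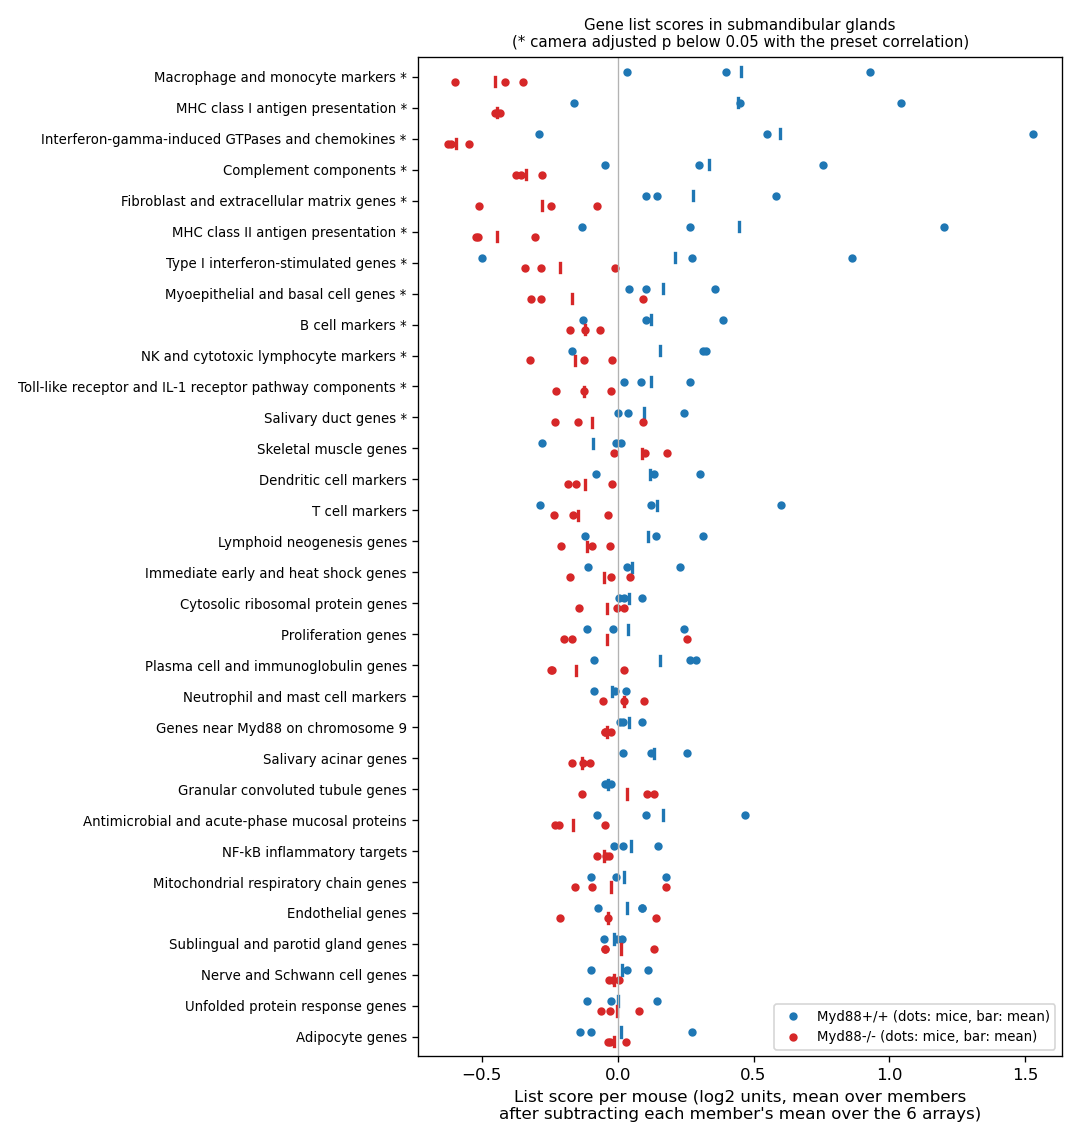
Scores of the 32 gene lists (y axis) in each submandibular gland (x axis, log2 units, the mean over members after subtracting each member's mean over the 6 arrays), with dots for mice, vertical bars for group means, blue for Myd88+/+ and red for Myd88−/−. An asterisk marks the 12 lists that camera called with its preset correlation, and the interferon-gamma list spreads from −0.29 to 1.53 among the Myd88+/+ mice against −0.63 to −0.55 among the Myd88−/− mice.

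Macrophage and monocyte markers fell, with 20 of 21 measured members lower and a mean log2 difference of −0.91 (camera adjusted p = 6.97e-15, and adjusted p = 0.427 with an estimated correlation). Of these members 14 passed adjusted over the list alone, all lower, and 0 over all genes. Csf1r, the receptor for the growth factor that macrophages need, read 9.46 ± 0.46 and 8.23 ± 0.24 (SD, n = 3 each), a 2.35-fold lower level, and C1qb, a subunit of complement C1q made by macrophages, read 8.44 ± 0.71 and 6.81 ± 0.20 (SD, n = 3 each). Ly6c2 was 2.10-fold lower, and Itgam, with a Myd88−/− mean of 5.04 under the background control median of 5.55, had −1.36. Complement components fell as well, by 0.67 on average with 15 of 17 members lower (camera adjusted p = 2.54e-08, and adjusted p = 0.427 with an estimated correlation), and 9 passed adjusted over the list alone against 0 over all genes. Besides C1qb and C1qc, which the macrophage list also holds, they included the inhibitor Serping1 with −1.08 and Cfp, which stabilises the alternative pathway, with −1.21.

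Both arms of antigen presentation fell. The MHC class I list had all 14 of 14 measured members lower, by −0.89 on average (camera adjusted p = 2.89e-10, and adjusted p = 0.427 with an estimated correlation), and 9 passed adjusted over the list alone against 0 over all genes. They included the immunoproteasome subunit Psmb8 with −1.51, the peptide transporter Tap1 with −1.59, B2m with −1.38 and H2-T22 with −0.71, the last from a family of near-identical genes that can share probes. The MHC class II list had 11 of 12 members lower, by −0.89 on average (camera adjusted p = 5.86e-06, and adjusted p = 0.55 with an estimated correlation), and 3 passed adjusted over the list alone against 0 over all genes. H2-Aa read 12.54 ± 0.94 and 10.59 ± 0.31 and H2-Eb1 10.76 ± 0.79 and 8.84 ± 0.36 (SD, n = 3 each). Ctss, a protease of antigen processing, had −1.04 (−1.41 to −0.65 without 1 mouse). H2-Ab1, whose groups overlapped, read 12.85 ± 1.46 and 11.18 ± 0.35 (SD, n = 3 each), a difference of −1.67 (−2.33 to −0.89 without 1 mouse). Without Myd88+/+ replicate 3 both lists stayed called, with means of −0.59 for class I and −0.51 for class II.

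Genes induced by interferon-gamma fell, with 18 of 19 members lower and a mean of −1.19 (camera adjusted p = 6.09e-10, and adjusted p = 0.55 with an estimated correlation). Adjusted over the list alone 12 passed lower and 1 higher, against 0 over all genes, the higher one being Ido1, named after its value of 0.75 was seen. Cxcl9 had −4.07, its relative Cxcl10 had −1.21 with a Myd88−/− mean of 4.43, under the background control median of 5.55, and the interferon-inducible GTPases Gbp2 and Irgm2 had −1.92 and −1.52. Without Myd88+/+ replicate 3 the list's mean was −0.72 and the call held, and without Myd88+/+ replicate 1 Cxcl9 passed on its own at −5.32 (limma adjusted p = 0.0295, range over all settings 0.0295 to 0.676). That mouse read 7.87, against 10.80 and 12.46 in the rest of its group, nearest to the Myd88−/− values. Leaving it out widens the difference, so this pass is no independent support. Type I interferon-stimulated genes fell by 0.42 on average, 24 of 29 being lower (camera adjusted p = 0.00115, and adjusted p = 0.635 with an estimated correlation), with 1 member passing adjusted over the list alone, Rtp4 at −1.69, and 0 over all genes. Bst2 and Trim30a had −0.93 and −1.06, while Ifi44l had 0.53. Both group means of Ifi44l, 4.24 and 4.77, lie under the background control median. That call rested on Myd88+/+ replicate 3, without which the mean was −0.10 and the adjusted p 0.415, and without Myd88+/+ replicate 1 the mean was −0.78. Type I scores of the groups overlapped (two-sided exact permutation p = 0.4).

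Components of Toll-like receptor and interleukin-1 receptor signalling, the pathway in which Myd88 acts, fell slightly, by 0.25 on average with 25 of 35 members lower (camera adjusted p = 0.00916, and adjusted p = 0.427 with an estimated correlation). Adjusted over the list alone 2 passed, against 0 over all genes. These were Unc93b1, which carries nucleic acid-sensing receptors to endosomes, with −0.91 and Cd180, a receptor of B cells and myeloid cells, with −1.54. Its partner Ly86 had −1.73 and Lbp, the binding protein for bacterial lipopolysaccharide, −0.76. Without Myd88+/+ replicate 3 the adjusted p was 0.113 and the call was lost.

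Targets of NF-kB, the transcription factor downstream of Myd88, were not called, with 14 members lower and 14 higher of 28 and a mean of −0.10 (camera adjusted p = 0.491). None passed adjusted over the list alone (0 of 28). Birc3, Bcl3 and Tnfaip3, which restrain inflammation or cell death, had −1.04, −0.68 and −0.56, and the chemokine gene Ccl4 had 0.41. Both group means of Bcl3 and the Myd88−/− mean of Tnfaip3 lie under the background control median of 5.55. Antimicrobial and acute-phase proteins of mucosa were not called either (mean −0.33, median 0.01, camera adjusted p = 0.458), as 9 of 23 members were lower and 14 higher. Adjusted over the list alone 4 passed lower and 1 higher, against 0 over all genes. The 4 were Pigr, the iron-binding Lcn2 with 8.13 ± 0.46 and 6.52 ± 0.57 (SD, n = 3 each), the copper carrier Cp with −0.84 and the lysozyme gene Lyz2 of macrophages with −1.91 (−2.43 to −1.22 without 1 mouse), and the higher one was the defensin gene Defb1 with 0.90, named after its value was seen. Without Myd88+/+ replicate 3 the list's mean was −0.18 (adjusted p = 0.778), whereas without the dimmest 50% of probe sets it was called lower (camera adjusted p = 0.0141).

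B cell markers fell by 0.24 on average, 15 of 19 being lower (camera adjusted p = 0.00465, and adjusted p = 0.572 with an estimated correlation), and 1 passed adjusted over the list alone, the adaptor gene Blnk with −0.85, against 0 over all genes. Cd72 had −0.78, Cxcr5 −0.44 and Fcmr −0.54. Both group means of Cxcr5, 4.84 and 4.40, and of Fcmr, 5.16 and 4.62, lie under the background control median of 5.55. The call was lost without Myd88+/+ replicate 3 (mean −0.11, adjusted p = 0.423) and without Myd88−/− replicate 2 (adjusted p = 0.0513), and without Myd88+/+ replicate 1 the mean was −0.37. NK and cytotoxic lymphocyte markers fell by 0.31, 12 of 16 being lower (camera adjusted p = 0.00707, and adjusted p = 0.572 with an estimated correlation), and 1 passed adjusted over the list alone, Klrb1c with −0.95, against 0 over all genes. Both group means of Klrb1c, 5.14 and 4.19, lie under the background control median of 5.55, as does the Myd88−/− mean of Ncr1, so the size of these differences is uncertain. The receptors Ncr1 and Klrk1 had −1.18 and −0.77 and the granzyme gene Gzma −0.88. That call was lost without Myd88+/+ replicate 3 (adjusted p = 0.186) and without Myd88−/− replicate 2 (adjusted p = 0.139), and without Myd88+/+ replicate 1 the mean was −0.48. Without the dimmest 50% of probe sets the means were −0.57 for B cell (adjusted p = 0.0375) and −0.82 for NK markers (adjusted p = 0.0469). That filter took out Cd72, Cxcr5, Fcmr, Klrb1c and Ncr1, and of the members named here it kept Blnk, Gzma and Klrk1. These means thus rest on few members and do not show a stronger fall of the whole lists. In both lists the scores of the groups overlapped (two-sided exact permutation p = 0.3 each).

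T cell markers were not called (13 of 17 lower, mean −0.29, camera adjusted p = 0.0604), with 0 passing adjusted over the list alone. Cd3e read 6.41 ± 1.64 and 4.98 ± 0.27 (SD, n = 3 each), Cd3g had −1.14, Cd4 −0.58, and Cd247 0.52. Without 1 mouse the difference of Cd3e ran from −2.08 to −0.51, that of Cd3g from −1.57 to −0.37 and that of Cd4 from −0.85 to −0.29. The Myd88−/− means of Cd3e and Cd3g lie under the background control median of 5.55. Without Myd88+/+ replicate 1 the list was called at a mean of −0.51 (adjusted p = 4.49e-05), and without Myd88−/− replicate 3 at −0.35 (adjusted p = 0.0191), while without Myd88+/+ replicate 3 its mean was −0.06 (adjusted p = 0.672). Dendritic cell markers were not called (8 of 14 lower, mean −0.24, camera adjusted p = 0.0591), though 2 passed adjusted over the list alone, Ccr9 with −1.12 and Bst2, against 0 over all genes. Both stand in other lists too, and over members of 1 list alone the mean was −0.05 (adjusted p = 0.672). Both group means of Ccr9, 4.86 and 3.73, lie under the background control median of 5.55. Xcr1 had −0.68 and Itgax −0.40, and both group means of Itgax and the Myd88−/− mean of Xcr1 lie under the same median. Without Myd88+/+ replicate 1 that list was called at an adjusted p of 0.00509, and without Myd88−/− replicate 3 at 0.00812, while without Myd88+/+ replicate 3 its mean was −0.15 (adjusted p = 0.364).

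Genes of lymphoid tissue formation were not called (13 of 19 lower, mean −0.22, camera adjusted p = 0.242), and 1 passed adjusted over the list alone, Cxcl13, against 0 over all genes. Cxcl12 had −0.59 and Lta 0.38 (0.14 to 0.55 without 1 mouse). The Myd88+/+ mean of Lta lies under the background control median of 5.55. Without Myd88+/+ replicate 1 the list was called at a mean of −0.34 (adjusted p = 0.0215), and without Myd88+/+ replicate 3 its mean was −0.12 (adjusted p = 0.508). Plasma cell and immunoglobulin genes were not called (5 of 9 lower, mean −0.31, camera adjusted p = 0.373, 0 adjusted over the list alone). Of the 18 genes written for that list only these 9 had a probe set, and its immunoglobulin constant genes had none. The lack of a call therefore says nothing about those transcripts. Jchain, which joins the subunits of secreted IgA, read 9.72 ± 1.82 and 7.53 ± 1.53 (SD, n = 3 each), with a difference of −3.03 to −1.22 without 1 mouse. Eaf2 had −0.50 (−0.77 to −0.32 without 1 mouse), Prdm1 −0.30 (−0.45 to −0.11) and Mzb1 0.20 (0.10 to 0.37). Both group means of Prdm1, 3.70 and 3.40, and of Mzb1, 3.71 and 3.91, lie under the background control median of 5.55. Neutrophil and mast cell markers were not called (11 of 17 higher, mean 0.04 as deposited, −0.02 after quantile normalization and −0.03 after cyclic loess, camera adjusted p = 0.429). The mast cell protease gene Cpa3 had −1.07, with a Myd88−/− mean of 5.38 under the background control median of 5.55. It was the 1 member to pass adjusted over the list alone, against 0 over all genes. Fcer1a had 0.56, Cma1 0.38 and Mmp8 0.32, but both group means of each of them lie under the same median. These rises are therefore not told apart from the higher readings of dim probe sets in Myd88−/− arrays.

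The secretory epithelium gave no call. Acinar genes had a mean of −0.26 and a median of −0.05, with 11 of 21 lower, 7 higher and 3 saturated (camera adjusted p = 0.457, 0 adjusted over the list alone). Bpifa2, a secreted salivary protein, read 8.57 ± 2.02 and 5.91 ± 0.43 (SD, n = 3 each). Its groups overlapped, as Myd88+/+ replicates 1, 2 and 3 read 9.35, 10.07 and 6.27, and Myd88−/− glands 5.55 to 6.38. Without Myd88+/+ replicate 3 its log2 difference was −3.81 and it passed limma's test (adjusted p = 0.0242, range over all settings 0.0242 to 0.682). That pass came from leaving out the 1 Myd88+/+ mouse within the Myd88−/− range. Bpifb2 had 0.34, the transcription factor gene Creb3l1 −0.28 (−0.39 to −0.10 without 1 mouse) and the chloride channel gene Ano1 0.25 (0.07 to 0.41). Both group means of Bpifb2, 3.36 and 3.70, lie under the background control median of 5.55. Prol1, Pip and Car6, singled out after their values were seen, were saturated on all 6 arrays. Granular convoluted tubule genes, which encode kallikreins and growth factors, had a mean of 0.07 with 13 of 21 higher, 5 lower and 3 saturated (camera adjusted p = 0.457, 0 adjusted over the list alone). Without Myd88−/− replicate 1 they were called higher at 0.16 (adjusted p = 0.0323). Their mean was 0.04 without Myd88−/− replicate 2 (adjusted p = 0.76) and 0.02 without Myd88−/− replicate 3 (adjusted p = 0.925). Klk1b16 had 0.46 (0.29 to 0.78 without 1 mouse), Esp15 0.54 (0.30 to 0.71), Bmp7 −0.29 and Smr3a 0.30 (0.10 to 0.50). Both group means of Esp15 and of Bmp7 lie under the background control median. Kallikrein genes are near-identical copies, so their separate values are uncertain, and Klk1, Klk1b5 and Klk1b26, also singled out afterwards, were saturated on all 6 arrays.

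Duct genes fell by 0.19 on average with 16 of 22 lower (camera adjusted p = 0.0129, and adjusted p = 0.572 with an estimated correlation), and 0 passed adjusted over the list alone. Duct scores of the groups overlapped (two-sided exact permutation p = 0.3). Ascl3 and Foxi1, transcription factors of ionocyte-like duct cells, had −0.96 and −0.60, Gstt1 −0.61 and the sodium channel subunit gene Scnn1g −0.62. The call was lost without Myd88+/+ replicate 1 (mean −0.12, adjusted p = 0.233), without Myd88−/− replicate 1 (mean −0.12, adjusted p = 0.164), after quantile normalization (adjusted p = 0.102) and after cyclic loess (adjusted p = 0.0904). Myoepithelial and basal cell genes fell by 0.34 with 12 of 14 lower (camera adjusted p = 0.00163, and adjusted p = 0.427 with an estimated correlation), and 1 passed adjusted over the list alone, Trp63, against 0 over all genes. The list scores of the 2 groups overlapped (two-sided exact permutation p = 0.2). Smooth muscle actin, Acta2, had −0.81, Cdh3 −0.39 and the keratin gene Krt14 −0.62.

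Fibroblast and extracellular matrix genes fell by 0.55 with 17 of 18 lower (camera adjusted p = 6.77e-08, and adjusted p = 0.427 with an estimated correlation), and 2 passed adjusted over the list alone against 0 over all genes, the collagen gene Col1a2 with −1.12 and the protease gene Mmp2 with −1.16. Skeletal muscle genes, of a tissue that lies next to the gland, were not called (15 of 18 higher, mean 0.18, camera adjusted p = 0.058), but were called higher without Myd88+/+ replicate 2 (adjusted p = 0.017), without Myd88+/+ replicate 3 (adjusted p = 0.028) and without Myd88−/− replicate 2 (adjusted p = 0.0289). Without Myd88+/+ replicate 1 their mean was 0.09 (adjusted p = 0.504). Ckm had −0.65 and Atp2a1 0.68. Endothelial genes (11 of 17 lower, mean −0.07, adjusted p = 0.696), nerve and Schwann cell genes (7 of 12 lower, mean −0.03, adjusted p = 0.859), adipocyte genes (8 of 17 lower, mean −0.02, median 0.09, adjusted p = 0.899) and sublingual and parotid gland genes (5 of 11 lower, 4 higher and 2 saturated, mean 0.03 as deposited, just under 0 after quantile normalization and −0.01 after cyclic loess, adjusted p = 0.827) were not called by camera. Prox1 and Eng of endothelium had 0.84 (0.55 to 1.02 without 1 mouse) and −0.87 (−1.54 to −0.34). Pmp22 and Nefl of nerve had −0.65 and 0.34 (0.12 to 0.54 for Nefl without 1 mouse). Lipe and Lpl of fat had −0.50 (−0.68 to −0.32) and −0.33 (−0.46 to −0.195). Tff2 and Prpmp5 of the other glands had 0.41 and 0.37 (0.13 to 0.58 for Prpmp5). Both group means of Nefl and Tff2, and the Myd88+/+ means of Atp2a1, Prox1 and Prpmp5, lie under the background control median of 5.55. In these 4 lists and the skeletal muscle list 0 members passed adjusted over the list alone.

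Genes that report on growth, stress and RNA handling gave no call. Proliferation genes had 17 of 23 lower and a mean of −0.08 (camera adjusted p = 0.373), with Aurka at 0.42 and Mki67 at −0.83 (−1.31 to −0.25 without 1 mouse), and were called lower without Myd88−/− replicate 2 (mean −0.22, adjusted p = 0.0273). Immediate early and heat shock genes had 16 of 22 lower and a mean of −0.10 (camera adjusted p = 0.306), with Dusp1 at −0.52 and Fos at 0.52. They were called lower without Myd88+/+ replicate 2 (adjusted p = 0.0448). Both group means of Aurka, 4.49 and 4.92, and of Fos, 3.69 and 4.21, lie under the background control median of 5.55. Unfolded protein response genes had 10 of 22 lower, a mean of −0.01 and a median of 0.02 (camera adjusted p = 0.881), with the chaperone genes Hyou1 at 0.47 and Pdia3 at −0.37. Mitochondrial respiratory chain genes (15 of 26 lower, mean −0.05, camera adjusted p = 0.604) included Ndufv1 at −0.61 and Ndufs1 at 0.37 (0.18 to 0.55 without 1 mouse), and cytosolic ribosomal protein genes (11 of 18 lower, mean −0.08, camera adjusted p = 0.371) included Rpl35 at −0.33 and Rpl8 at −0.26. The means of the mitochondrial and unfolded protein lists changed sign after quantile normalization and cyclic loess, and that of the ribosomal list after quantile normalization. In these 5 lists 0 members passed adjusted over the list alone.

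The strain labels name a congenic background, so genes next to Myd88 on chromosome 9 were compared with the rest. Of 155 genes within 10 Mb, 0 passed limma's adjusted test, as did 0 of 19349 elsewhere, and at an unadjusted p under 0.05 there were 11 and 1912. Within 5 Mb and 20 Mb it was 0 of 100 and 0 of 299. At an unadjusted p under 0.01 they were 5 of 155 (3.23%) and 484 of 19349 (2.5%, two-sided Fisher's exact p = 0.599). The 5 were the chemokine receptor genes Ccr2 with −1.57, Ccr9 with −1.12 and Cx3cr1 with −0.99, together with Cmtm8 with −0.62 and Crtap with −0.57, the last 2 named after their values were seen. The fixed list of neighbours was not called, with 34 of 71 lower, a mean of −0.08 and a median of 0.00 (camera adjusted p = 0.429, 0 adjusted over the list alone). Ttc21a in that list had 0.55. Both group means of Ttc21a and of Ccr9, and the Myd88−/− mean of Cx3cr1, lie under the background control median of 5.55.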

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

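The tests of a lymph node, of swapped labels, of a linked segment and of the ERCC controls, and the intervals of the pooled immune score, were chosen only after the results they bear on were seen. Control probe sets stand outside the comparisons, and 2 of their 5 classes gave a signal that separated the groups. The 23 background control probe sets averaged 5.037 in Myd88−/− arrays (range 5.028 to 5.05) and 4.977 in Myd88+/+ arrays (4.963 to 4.998), a difference of 0.0595 log2 units. The 63 ERCC control probe sets averaged 4.878 (4.815 to 4.924) and 4.742 (4.703 to 4.794), a difference of 0.136. In both classes all 3 Myd88−/− arrays lay above all 3 Myd88+/+ arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). The other 3 classes overlapped between the groups.

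Probe sets near background lay higher, and bright ones lower, in Myd88−/− arrays. Among 1412 olfactory and vomeronasal receptor genes, most of which a salivary gland should not express, the median log2 difference was 0.137, with 73.4% higher. It was 0.0569 after quantile normalization and 0.0498 after cyclic loess, so a compressed range of the arrays cannot be told apart from other causes, because part of the shift went and part stayed. The ERCC controls, which take no signal from mouse genes, had a median difference of 0.0822, more than 50% of the receptor value, which is consistent with a higher background on the Myd88−/− arrays. The receptor median stood at percentile 100 of 10000 random lists matched on signal level (median 0.0877, middle 95% from 0.0733 to 0.101). A change in the receptor genes themselves, or in probes of their kind, therefore stays open, as does an effect of genotype on RNA composition.

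The macrophage, MHC class I, MHC class II, interferon-gamma and complement lists lay lower in Myd88−/− glands. A compressed range of the arrays is argued against, since the mean over their 80 genes was −0.869 after quantile normalization and −0.904 as deposited, while 10000 lists matched on signal level ranged from −0.164 to 0.119. A single strongly inflamed Myd88+/+ gland cannot be told apart. Without any 1 Myd88+/+ gland 5 of the 5 lists stayed called. The 3 splits that put Myd88+/+ replicate 3 with 2 Myd88−/− arrays called 0 of them. Both go against it, but these calls leave out the spread between mice. Without Myd88+/+ replicate 3 the pooled score differed by −0.59 with a 95% confidence interval of −1.22 to 0.035. Without replicate 2 of that group it differed by −0.933 (−2.36 to 0.496), and without replicate 1 by −1.19 (−2.02 to −0.362). An interval that includes 0 is thus not particular to leaving out replicate 3. A lymph node taken along with Myd88+/+ glands cannot be told apart: T and B cell markers differed less than macrophage markers by 0.631 (standard error 0.184), but only 4 of 12 of the former lay over 2 log2 units above background, against 14 of 18 of the latter. The genotype and untested differences in litter, housing or the degree of inflammation between mice stay open.

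Myd88 itself lay only slightly lower. The gap between the lowest Myd88+/+ and the highest Myd88−/− value was 0.061 log2 units, against a gap of 0.267 in the pooled immune score, so an array with the wrong genotype label cannot be told apart from a probe set outside the deleted part, whose place in the gene is not given in the sources used here. A donor segment around Myd88 cannot be told apart either, because the odds ratio for an unadjusted p under 0.01 near Myd88 was 1.3 with an interval of 0.414 to 3.12, which leaves both no excess and a 3-fold excess possible.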

How the results depend on the processing

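Leaving saturated probe sets out of the lists and counting probe sets at an unadjusted p under 0.05 were chosen only after the results were seen. Values below are camera's adjusted p unless another test is named, and where a call or a sign moved, the cause was not tested. The macrophage, complement, MHC class I, MHC class II, interferon-gamma, fibroblast and myoepithelial lists were called lower in 17 of 19 settings, the exceptions being the estimated correlation and fry. All 17 kept the preset correlation of 0.01, so they do not test whether the calls hold when members vary together from mouse to mouse. In the same order of lists the estimated correlation between members was 0.41, 0.41, 0.60, 0.61, 0.69, 0.34 and 0.11. With the estimated correlation the adjusted p was 0.427 for complement, fibroblast, macrophage, MHC class I, myoepithelial and Toll-like receptor lists, 0.55 for interferon-gamma and MHC class II, 0.572 for B cell, NK and duct, and 0.635 for type I interferon. With fry the same groups of lists had 0.283, 0.40, 0.457 and 0.563. Limma called 0 genes lower as reported, 2 with median centring and 4 with an intensity trend and robust variances, and 0 to 5 without 1 mouse, against 1233 at an unadjusted p under 0.05. At least 2-fold apart at an unadjusted p under 0.05 were 177 probe sets, 100 without variance moderation and 137 to 318 without 1 mouse. Higher at an unadjusted p under 0.05 were 999, with 619 after leaving out the dimmest 30% and 323 after the dimmest 50%, which test fewer probe sets. Near Myd88, 5 genes passed an unadjusted p under 0.01 and 0 the adjusted test. Called only under another setting were, after quantile normalization, dendritic cell (0.00978) and T cell markers (0.0141); after median centring dendritic cell, skeletal muscle and T cell lists (0.0426 each); after cyclic loess dendritic cell (0.0125) and T cell (0.0184); with array weights dendritic cell (0.041) and T cell (0.0334); with the mean of a gene's probe sets dendritic cell (0.0442); and without the dimmest 50% antimicrobial proteins (0.0141). Duct genes, with a mean of −0.19 as reported, lost their call after quantile normalization (mean −0.12, 0.102), cyclic loess (−0.13, 0.0904) and without the dimmest 30% (−0.19, 0.0861) or 50% (−0.20, 0.291). The last setting also ended the call of the Toll-like receptor list (0.0503), whose mean was −0.35 there and −0.25 as reported. With both filters the means did not shrink, and each list was compared with fewer other genes. The level compared with moved as well, as the median log2 difference was 0.02 over all tested probe sets and −0.07 in the brighter 50%. Camera's direction turned, in lists that were not called, after quantile normalization for ribosomal (1.0), mitochondrial (0.46), sublingual and parotid (0.998) and unfolded protein response genes (0.402), and after cyclic loess for mitochondrial (0.437), sublingual and parotid (0.957) and unfolded protein response genes (0.461). It turned without the dimmest 30% for neutrophil and mast cell markers (0.693) and the unfolded protein response (0.723), and without the dimmest 50% for genes near Myd88, skeletal muscle and T cell lists (0.946 each), mitochondrial (0.716), nerve (0.967) and unfolded protein response genes (0.545). With array weights it turned for adipocyte genes (0.798). The mean alone changed sign, without camera's direction, for neutrophil and mast cell markers after quantile normalization (−0.02) and cyclic loess (−0.03), and for the unfolded protein response with array weights (to 0.000441). Without the dimmest 50% the neutrophil and mast cell list gave no value, because fewer than 2 of its members were left. Without 1 mouse in turn the adjusted p ran from 3.18e-06 to 0.423 for B cell, 4.82e-06 to 0.186 for NK, 0.00269 to 0.113 for Toll-like receptor, 8.86e-14 to 0.415 for type I interferon, 0.00136 to 0.233 for duct, 0.00509 to 0.364 for dendritic cell, 4.49e-05 to 0.672 for T cell, 0.0215 to 0.536 for lymphoid tissue formation, 0.017 to 0.504 for skeletal muscle, 0.0448 to 0.859 for immediate early, 0.0323 to 0.925 for granular tubule and 0.0273 to 0.905 for proliferation genes, whose direction turned without Myd88+/+ replicate 3. In the same settings it ran, for lists that were never called and whose direction turned, from 0.308 to 0.925 for adipocyte, 0.307 to 0.941 for endothelial, 0.108 to 0.966 for mitochondrial, 0.598 to 0.969 for nerve, 0.57 to 0.849 for sublingual and parotid and 0.437 to 0.925 for unfolded protein response genes. Among 122 named genes 1766 values held 0 changes of sign, and 38 genes moved by over 1.5 times without 1 mouse. With the replicate block, 0 genes were called, 181 probe sets were at least 2-fold apart at an unadjusted p under 0.05, skeletal muscle (0.0458) and T cell (0.0313) lists became called, and no other call changed. The replicate numbers do not pair the mice: deviations of same-numbered arrays correlated at −0.113, −0.155 and −0.019, and no array correlated best with its own number. Signal over background limits the dimmer 50% of probe sets, where a difference is shrunk.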

Other observations

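The pan-leukocyte test, the comparison with each leukocyte list and the genes named in this part were chosen only after their values were seen, and the sterol list was chosen after the value of Insig1 but before its own. Several genes outside the lists lay far apart between the groups. Fcer1g, the shared chain of activating Fc receptors on myeloid cells, read 8.63 ± 0.86 in Myd88+/+ and 6.55 ± 0.34 in Myd88−/− glands (SD, n = 3 each), a log2 difference of −2.08 that was −2.58 and passed limma's test without Myd88+/+ replicate 1 (adjusted p = 0.0295, and 0.321 with all mice). The mouse left out read 7.64, against 9.15 and 9.10, the nearest of its group to the Myd88−/− values. Plbd1, a phospholipase of myeloid granules, read 9.61 ± 0.98 and 7.50 ± 0.16 (SD, n = 3 each). Ccl8, a chemokine of tissue macrophages, had a log2 difference of −2.53, Retnla, made by alternatively activated macrophages, −2.05, and Slc37a2, a sugar-phosphate transporter of macrophages, −1.91. Igfbp5, a binding protein for insulin-like growth factors, read 11.88 ± 0.10 and 10.11 ± 0.87 (SD, n = 3 each), and passed without Myd88−/− replicate 2 at −2.27 (limma adjusted p = 0.0267, and 0.321 with all mice). That replicate read 11.11, against 9.69 and 9.54, the nearest of its group to the Myd88+/+ values, so neither of these 2 passes is independent support. The neurotrophin receptor gene Ntrk2 had −1.43.

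On the higher side, Insig1, which holds back sterol synthesis and is itself induced with it, read 12.02 ± 0.58 and 13.35 ± 0.75 (SD, n = 3 each). The sterol synthesis genes Hmgcs1, Idi1, Cyp51 and Fdps had 0.51, 0.51, 0.77 and 0.68, and the transcription factor gene Srebf2 had 0.32, while Ebp had −0.37 with all Myd88−/− values below all Myd88+/+ values, Mvk −0.17, Stard4 −0.14, Lss 0.04, Dhcr7 0.05 and Sc5d 0.02. Ccn1, a matricellular protein, had 1.10, Ddah1, which breaks down an inhibitor of nitric oxide synthesis, had 1.05 and Gucy2c, a receptor of epithelial cells for guanylin peptides, had 1.19.

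Sterol synthesis may be slightly higher in Myd88−/− glands. The 18 sterol genes other than Insig1 had a mean of 0.224 with 4 lower (camera p = 0.00855, and p = 0.354 with an estimated correlation), but the 95% confidence interval of their score ran from −0.284 to 0.731 and the scores of the groups overlapped (two-sided exact permutation p = 0.3). The mean goes with the hypothesis, but the interval includes 0, so an absence of any difference stays open too.

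Whether Myd88−/− glands hold fewer leukocytes of all kinds stays open. The 23 pan-leukocyte genes, none of which stands in another list, had a mean of −0.673 with 21 lower (camera p = 4.61e-10, and p = 0.113 with an estimated correlation), an interval of −1.53 to 0.188 and scores that did not overlap (two-sided exact permutation p = 0.1). Because the list was chosen after the lower immune lists were seen, and its interval includes 0, it does not decide the question. Of 7 leukocyte lists 6 had a lower mean, of which the T cell, dendritic cell and plasma cell lists were not called, and neutrophil and mast cell markers had 11 of 17 higher with a mean of 0.04 that turned to −0.02 after quantile normalization, −0.03 after cyclic loess and −0.14 without the dimmest 30%, so they count neither way. Ptprc, the common leukocyte antigen, read 10.21 ± 1.11 and 8.59 ± 0.31 (SD, n = 3 each), Cd52 had −1.83 and Hcls1 −1.17. A bulk measurement does not part fewer cells from less transcript per cell, and genotype stays confounded with anything that differed between the groups of mice.

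The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2232 probe sets at an unadjusted p under 0.05 against at most 1991 in another, with 1 split as large, itself, and 177 at least 2-fold apart against at most 61, again 1 split. It gave 0 at an adjusted p under 0.05 against 0, with 10 splits as large. For lists called it gave 12 against at most 14, with 4 splits as large, the other 3 being those that group Myd88+/+ replicate 1 with 2 Myd88−/− arrays (14, 14 and 13 lists). In each of those 3 splits the macrophage, MHC class I, MHC class II, interferon-gamma and complement lists were among the calls (5 of 5).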
